A study of Mus musculus with 24 samples.

How the data were processed

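RNA from sorted mouse spleen T cells was measured by poly(A) RNA sequencing in 24 libraries, 4 in each of 6 groups made by 2 cell types (CD4 and CD8) and 3 genotypes. Groups and replicate numbers were taken from the labels. The labels do not say that the numbers mark separate animals, so the p-values measure the spread between these samples, part of which may be technical.

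The raw gene counts are the whole-number counts the authors deposited, for 55401 genes in each library. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.35, STAR 2.7.1a was used with the genome build GRCm38, and DESeq2 1.26.0 was named, with no further settings. The annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited count table opens with summary lines for unmapped, multimapping, featureless and ambiguous reads. These were kept out of library sizes and tests, and held 31.6% to 35.0% of all entries of a library. Multimapping reads, 17.5% to 18.5%, were not counted for any gene in the deposited table. A gene with a near-identical copy therefore keeps only its uniquely placed reads. The deposited normalized signal is the raw counts divided by 1 factor per library (0.840 to 1.558), and lists 20961 genes. The lowest total raw count among listed genes was 10 and the highest among genes not listed was 9. The normalized table was used in 1 alternative only.

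The deposited gene identifiers were matched to the reference annotation of GRCm38: 54349 of 55401 genes had the same identifier, version and coordinates, and 24645 genes had a total count of 0. The number of columns of per-sample values left unused was 0. Total gene counts ran from 11.9 to 21.8 megacounts per library, with a median of 14.0 megacounts. A count of 3, taken as the floor per library, was 0.138 to 0.251 CPM (counts scaled to the library total). Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Libraries of 1 group were compared for duplicates: the lowest chi-square per degree of freedom over 36 pairs was 2.62 (median 14.2), so every pair differed by more than sampling noise.

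Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr (its default count of 10), which left 12719 genes in CD4 libraries, 12612 in CD8 libraries and 13288 over all libraries. Libraries were scaled with TMM factors (0.976 to 1.02). Genotypes were compared within a cell type in a fit of its 12 libraries, with 9 residual degrees of freedom. Both differences of genotype effects between cell types, and CD8 against CD4 wild type, came from a fit of all 24 libraries with 18 residual degrees of freedom. The common biological coefficient of variation was 0.161 in CD4, 0.155 in CD8 and 0.158 over all libraries. Each gene was tested with edgeR's quasi-likelihood F test, 2-sided, and was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. Standard errors are the log2 change over the square root of F. Values per gene are TMM-normalised CPM with the SD over 4 libraries.

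Gene lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, where at least 4 members were tested. This left 27 lists per comparison, with Benjamini-Hochberg adjustment over them. Each list was also tested with camera's estimated correlation and with fry. Markers of gamma delta T cells, plasma cells, macrophages, neutrophils, NK cells, red cells and platelets had fewer than 4 tested members in these cells and were used only as scores per library. Scores and quality measures, 19 per comparison, were compared with an exact 2-sided permutation test over all 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286. Called genes within 10 Mb of Pou2af1 were compared with genes elsewhere by Fisher's exact test, 2-sided. Correlations of fold changes between comparisons with the same wild-type libraries were set beside 20 simulated pairs of unchanged groups and 6 splits of those libraries.

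The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Pou2af1 and, per comparison, the called genes of largest change each way (up to 12 for knockout against wild type, up to 5 otherwise) with a mean of at least 1 CPM and no overlap between the groups. It leaves out genes known only by a Gm or Rik name and receptor segments. Where fewer than 3 genes pass, the 3 of lowest p each way are named as not passing, and each list gives up to 4 members of lowest p.

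Whether replicate numbers pair libraries was checked from the correlation of their deviations from the group means. Within CD4 libraries every same-numbered pair lay above 0.1 (0.395 to 0.624 for knockout with wild type, 0.127 to 0.379 for heterozygote with wild type, 0.218 to 0.510 for knockout with heterozygote). Between CD4 and CD8 libraries of 1 genotype and number, 12 of 12 pairs did (0.147 to 0.451). Within CD8 libraries they did not (the lowest were 0.0464, -0.264 and 0.0756). A CD4 library was closest to its own number in 2 of 4 pairs for knockout with wild type. It was in 3 of 4 for heterozygote with wild type and 1 of 4 for knockout with heterozygote. A correlation above 0.1 alone therefore does not show pairs. The sign was stronger between cell types. There a CD4 library was closest to its own number among the CD8 libraries of its genotype in 10 of 12 cases. Both libraries were of the same sex in 12 of 12 pairs. The main fit of all 24 libraries did not pair them. The pairing is read from the data, not from the labels.

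The test was tried on simulated counts drawn from the means and library sizes of each comparison, with 200 genes changed. The simulated libraries are independent and lack the difference between replicates 1 and 2 and replicates 3 and 4. The shares below may therefore not hold for the data. For CD4 knockout against wild type (12719 genes) edgeR recovered 46.3% of genes changed 1.5-fold, 76.1% at 2-fold and 92.4% at 4-fold, and 6.54% of calls were false. The same shares were 38.8%, 82.1% and 95.5% (4.0% false) for CD8 knockout against wild type, 50.7%, 76.1% and 92.4% (2.67%) for CD4 heterozygote against wild type, and 44.8%, 68.7% and 84.8% (2.22%) for CD8 heterozygote against wild type. They were 50.7%, 77.6% and 87.9% (7.10%) for CD4 knockout against heterozygote, and 46.3%, 71.6% and 89.4% (5.48%) for CD8 knockout against heterozygote. They were 26.9%, 62.7% and 83.3% (1.71%) for the knockout effect between cell types, 25.4%, 61.2% and 89.4% (4.88%) for the heterozygote effect, and 49.3%, 73.1% and 92.4% (5.30%) for CD8 against CD4 wild type. DESeq2 1.42.0 on the same simulated counts gave 18.6% false calls for CD4 knockout against wild type, 10.9% for CD4 heterozygote against wild type, 14.4% for CD8 knockout against heterozygote and 6.11% to 15.2% for the other 6 comparisons.

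The alternatives fixed in advance were DESeq2's Wald test, RLE factors, no filter on low counts, a filter of 1 CPM in 4 libraries, limma on the deposited normalized counts, other sets of libraries in the fit, the replicate number as a block, a B cell score as a covariate, sex as a covariate, and leaving out each library of the groups compared. For comparisons between cell types the replicate block was genotype and number together, which joins a CD4 library with a CD8 library. Sex was read from whether Xist exceeded the Y-linked gene Ddx3y in normalised CPM. Alternatives that use the difference between replicates 1 and 2 and replicates 3 and 4 were chosen after the data had been seen, from the first principal component. The values of some single genes are not reported here.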

Results

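Transcripts were measured in CD4 and CD8 T cells sorted from mouse spleen and activated in culture for 2 days through CD3 and CD28. The mice were 12 weeks old and of the C57BL/6 strain. The study asks what Pou2af1 does in these cells. Pou2af1 encodes a coactivator that binds the octamer factors POU2F1 and POU2F2 and is best known from B cells. Wild-type controls were Cre-negative with both alleles floxed by their genotype label, although their titles call them +/+. Heterozygotes carried CD4-Cre with 1 floxed allele, and knockouts carried CD4-Cre with both alleles floxed. Each of the 6 groups held 4 libraries, 24 in all. Gene counts per library, in megacounts (M), ran from 13.9 to 21.8 M in CD4 wild type, 11.9 to 16.6 M in CD4 heterozygotes and 12.0 to 13.9 M in CD4 knockouts. They ran from 12.6 to 15.9 M in CD8 wild type, 13.3 to 14.7 M in CD8 heterozygotes and 14.4 to 16.6 M in CD8 knockouts. By Xist against the Y-linked gene Ddx3y, wild-type and knockout groups held 1 female and 3 male libraries each and heterozygous groups 2 and 2.

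Pou2af1 (ENSMUSG00000032053.8, GRCm38 chromosome 9, 51213708 to 51240080) followed the genotype labels in every library. In CD4 cells its normalised count was 38.4 ± 10.95 CPM in wild type, 20.2 ± 4.29 CPM in heterozygotes and 2.20 ± 1.11 CPM in knockouts (SD, n = 4 each), so heterozygotes held 52.5% and knockouts 5.72% of the wild-type mean. In CD8 cells it was 27.7 ± 6.18, 15.5 ± 1.40 and 1.71 ± 0.751 CPM (SD, n = 4 each), 56.1% and 6.19% of wild type for the Cre carriers. No knockout library exceeded 3.79 CPM in CD4 or 2.44 CPM in CD8, and no wild-type library was below 28.6 or 21.9 CPM. Raw counts were 18 to 52 in CD4 knockouts and 11 to 36 in CD8 knockouts, above the floor of 3 counts. The knockout change was -4.13 on the log2 scale in CD4 (SE 0.32, edgeR quasi-likelihood adjusted p = 5.93e-05) and -4.0 in CD8 (SE 0.26, edgeR quasi-likelihood adjusted p = 4.93e-06), Benjamini-Hochberg adjusted.

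**Figure D1:**
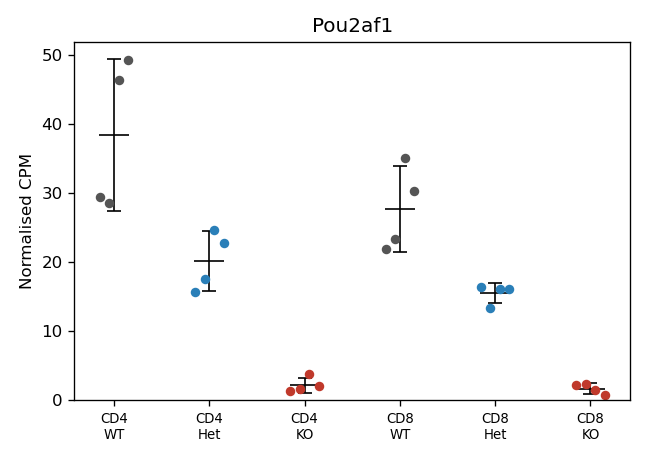
Normalised counts (CPM) of Pou2af1 in each library by cell type and genotype, with bars for mean ± SD over 4 libraries. Pou2af1 steps down from wild type to heterozygote to knockout in both cell types, with CD4 means of 38.4, 20.2 and 2.20 CPM.

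The heterozygote change of Pou2af1 was -0.94 in CD4 (SE 0.26, edgeR quasi-likelihood adjusted p = 0.344) and -0.84 in CD8 (SE 0.21, edgeR quasi-likelihood adjusted p = 1.0), and neither passed over all genes. For this gene, named in advance, the edgeR quasi-likelihood unadjusted p was 0.00337 in CD4 and 0.00163 in CD8. The highest heterozygote library stood at 24.7 CPM in CD4 and 16.4 CPM in CD8. The lowest wild-type library stood at 28.6 and 21.9 CPM, so the groups did not overlap. With the replicate number as a block, the CD4 change was -0.92 and passed (edgeR quasi-likelihood adjusted p = 0.00162, in a range of 7.39e-05 to 0.754 over all alternatives). Knockouts lay below heterozygotes by -3.19 in CD4 (SE 0.32, edgeR quasi-likelihood adjusted p = 0.00245) and -3.16 in CD8 (SE 0.26, edgeR quasi-likelihood adjusted p = 0.000125). Without a filter on low counts the CD4 comparison with heterozygotes did not pass (edgeR quasi-likelihood adjusted p = 0.0845, the highest over its alternatives, of which the lowest was 5.81e-24).

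The main question was what loss of Pou2af1 changes in activated CD4 cells. Knockouts carry Cre and the controls do not, so this comparison alone cannot part loss of Pou2af1 from Cre. Beside Pou2af1, the named genes that changed were a pair of cytoskeletal and ribosomal genes and a copy of each. Rps3a1, which encodes a protein of the small ribosomal subunit (GRCm38 chromosome 3, 86137940 to 86142702), fell from 512 ± 34.8 to 268 ± 10.9 CPM (SD, n = 4 each; log2 change -0.94, SE 0.06, edgeR quasi-likelihood adjusted p = 6.73e-06). Its copy Rps3a3 (chromosome 13, 108670603 to 108671397) rose from 2.24 ± 0.175 to 199 ± 6.16 CPM (log2 change 6.47, SE 0.07, edgeR quasi-likelihood adjusted p = 5.47e-15). Tpm3, a tropomyosin that lies along actin filaments (chromosome 3, 90072649 to 90100902), fell from 263 ± 9.50 to 179 ± 6.38 CPM (log2 change -0.56, SE 0.06, edgeR quasi-likelihood adjusted p = 0.00147). Its related sequence Tpm3-rs7 (chromosome 14, 113314608 to 113316754) rose from 6.21 ± 0.695 to 78.2 ± 3.19 CPM (log2 change 3.65, SE 0.09, edgeR quasi-likelihood adjusted p = 7.45e-11). The sequences of the genes and their copies were not compared. Reads that fit more than 1 place were not counted, so the levels of all 4 genes are uncertain.

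The other 4 calls in CD4 knockouts lie outside the naming rule and were chosen after their values were seen. Gm38326 (GRCm38 chromosome 3, 60788361 to 60794730) rose from 0.206 ± 0.0939 to 7.09 ± 0.503 CPM (SD, n = 4 each; edgeR quasi-likelihood adjusted p = 1.72e-07). Its neighbour Gm33707 (chromosome 3, 60769887 to 60770455) rose from 0.0703 ± 0.101 to 2.23 ± 0.841 CPM (edgeR quasi-likelihood adjusted p = 0.00202). Gm8778 (chromosome 6, 128976866 to 128977972) rose from 0.0281 ± 0.0337 to 1.33 ± 0.690 CPM (edgeR quasi-likelihood adjusted p = 0.00414). 2010007H06Rik (chromosome 9, 51278513 to 51284210), which lies next to Pou2af1, rose from 0.98 ± 0.468 to 9.37 ± 4.52 CPM (edgeR quasi-likelihood adjusted p = 0.00718). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 9 of 12719 genes, 6 higher and 3 lower, and 305 genes had an unadjusted p under 0.05 where chance gives 636. The fit leaves the difference between replicates 1 and 2 and replicates 3 and 4 in the residual spread, which can raise p-values. Few calls therefore do not show few effects, here or in later comparisons with counts under the chance value. With that difference as a covariate, chosen after the data had been seen, 11 genes were called. Within replicates 1 and 2 alone 10 genes were called and within replicates 3 and 4 alone 11. Gm33707 passed in 21 of 22 alternatives and 2010007H06Rik in 19 of 22, while Gm8778 passed in neither set of replicates alone.

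In CD4 knockouts no member of the 27 gene lists was called by edgeR's quasi-likelihood test over all genes or adjusted over the list alone. Of 9 tested partners and reported T cell targets of POU2AF1, 0 rose and 0 fell, and the member of lowest p, the octamer factor gene Pou2f1, had a log2 change of -0.17 (SE 0.08). Among 28 type I interferon response genes 27 lay above wild type with a median log2 change of 0.35, as for Ifit3 (0.89, SE 0.47) and Oasl2 (0.56, SE 0.30). camera called that list higher (adjusted p = 2.91e-07), which did not hold with an estimated correlation (adjusted p = 0.790). The p53 target list was also called higher (camera adjusted p = 0.00284, and adjusted p = 0.790 with an estimated correlation), with Gtse1 at 0.18 (SE 0.07) and Pmaip1 at 0.47 (SE 0.20). With the replicate number as a block, camera called 4 lists in place of 2, and 0 with an estimated correlation. fry called 0 lists.

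CD8 cells were compared in the same way to ask what Pou2af1 does there, with the same limit that only the knockouts carry Cre. The same copies moved: Rps3a3 rose from 2.04 ± 0.453 to 179 ± 14.1 CPM (SD, n = 4 each; log2 change 6.45, SE 0.12, edgeR quasi-likelihood adjusted p = 2.38e-12) and Tpm3-rs7 rose from 6.50 ± 0.662 to 81.6 ± 5.37 CPM (log2 change 3.65, SE 0.08, edgeR quasi-likelihood adjusted p = 6.16e-12). Rps3a1 fell from 467 ± 10.7 to 246 ± 25.5 CPM (log2 change -0.92, SE 0.07, edgeR quasi-likelihood adjusted p = 3.18e-05), and Tpm3 fell from 283 ± 8.36 to 190 ± 7.14 CPM (log2 change -0.57, SE 0.05, edgeR quasi-likelihood adjusted p = 0.000128). Cd1d1, which presents lipid antigens to natural killer T cells (GRCm38 chromosome 3, 86995834 to 86999441), fell from 3.47 ± 0.405 to 1.48 ± 0.224 CPM (log2 change -1.22, SE 0.18, edgeR quasi-likelihood adjusted p = 0.0155). Cd1d1 passed in 11 of 22 alternatives and in neither set of replicates alone. 2010007H06Rik rose from 0.581 ± 0.340 to 4.95 ± 0.294 CPM (edgeR quasi-likelihood adjusted p = 0.000572), and Gm8778 also passed. Gm8778 passed in neither set of replicates alone and 2010007H06Rik did not pass in replicates 1 and 2. Both lie outside the naming rule, and were chosen after their values were seen.

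Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 8 of 12612 in CD8 knockouts, 4 higher and 4 lower, and 361 had an unadjusted p under 0.05 where chance gives 631. Replicates 1 and 2 alone gave 5 calls and replicates 3 and 4 alone gave 5, the latter without Tpm3. No member of the 27 lists was called over all genes. Adjusted over the list alone, edgeR's test called the follicular helper gene Slamf6 lower (log2 change -0.30, SE 0.08) and the stress-induced factor gene Atf3 higher in the immediate early list (0.70, SE 0.19). All 28 interferon response genes lay above wild type, with a median of 0.65. All 20 cholesterol synthesis genes lay below wild type, with a median of -0.35 and with Nsdhl at -0.41 (SE 0.13). camera called these lists (adjusted p = 1.60e-11 and 4.21e-12), and neither call held with an estimated correlation (adjusted p = 0.724 for each). Its calls for oxidative phosphorylation (lower), immediate early genes (higher) and the unfolded protein response (higher) had adjusted p = 0.907, 0.724 and 0.724 with an estimated correlation, and fry called 0 lists.

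Heterozygotes against wild type ask what loss of 1 allele does, again with the limit that the heterozygotes carry Cre and the controls do not. In CD4 cells the 4 copy genes changed as in knockouts: Rps3a3 by 6.38 on the log2 scale, Tpm3-rs7 by 3.63, Rps3a1 by -1.0 and Tpm3 by -0.57. Tmod3, a tropomodulin that caps actin filaments (GRCm38 chromosome 9, 75497707 to 75559657), fell from 218 ± 16.7 to 118 ± 3.76 CPM (SD, n = 4 each; log2 change -0.90, SE 0.07, edgeR quasi-likelihood adjusted p = 4.73e-05). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose from 103 ± 12.7 to 164 ± 10.9 CPM (log2 change 0.66, SE 0.10, edgeR quasi-likelihood adjusted p = 0.0303). Ehd4, which acts in endocytic traffic, rose from 52.5 ± 1.78 to 68.6 ± 2.46 CPM (log2 change 0.38, SE 0.06, edgeR quasi-likelihood adjusted p = 0.0412). Neat1, the RNA that scaffolds paraspeckles, fell from 57.8 ± 10.1 to 32.5 ± 2.11 CPM (log2 change -0.84, SE 0.13, edgeR quasi-likelihood adjusted p = 0.0374). Cdkn1a, Ehd4 and Neat1 passed in 14, 9 and 13 of their 22 alternatives.

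In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 11 of 12719 genes in CD4 heterozygotes, 7 higher and 4 lower, among them Gm38326 (8.17 ± 1.09 CPM, n = 4), Gm33707 and Gm8778, named after their values were seen. At an unadjusted p under 0.05 stood 1093 genes where chance gives 636. DESeq2 called 80. With the replicate number as a block edgeR called 58, 29 higher and 29 lower, which hold the p53 targets Pmaip1 (log2 change 0.80), Gtse1 (0.40) and Mdm2 (0.29), the chemokine gene Ccl4 (0.67) and the octamer factor gene Pou2f2 (-0.32). Replicates 1 and 2 alone, where both heterozygotes are female and both wild types male, gave 365 calls, so sex and genotype are not separable there, and replicates 3 and 4 alone gave 103. The difference between replicates 1 and 2 and replicates 3 and 4 as a covariate gave 82, and with sex added 507, both chosen after the data had been seen. With all 24 libraries in the fit 18 were called. With replicate 3 of wild type or replicate 1 of the heterozygotes left out, 7 were called in either case.

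In CD4 heterozygotes the p53 target list, genes of cell cycle arrest and apoptosis, held the most members past the test. Of 15 tested, 1 rose over all genes and 7 rose when adjusted over the list alone, with 0 lower, including Cdkn1a, Gtse1 (log2 change 0.40, SE 0.07), Mdm2 (0.29, SE 0.07) and Pmaip1 (0.78, SE 0.20) in edgeR's quasi-likelihood test. camera called the list higher (adjusted p = 8.12e-07, and adjusted p = 0.159 with an estimated correlation). Of 17 cytotoxic effector genes 0 passed over all genes and 2 rose when adjusted over the list alone, the cytokine gene Ifng (log2 change 1.56, SE 0.42) and the perforin gene Prf1 (1.46, SE 0.41), with camera adjusted p = 2.50e-06, and adjusted p = 0.105 with an estimated correlation. Of 9 POU2AF1 partners and reported targets, 1 rose (Ifng) and 2 fell (Pou2f2 by -0.32, SE 0.11, and Pou2f1 by -0.22, SE 0.08) when adjusted over the list alone, and camera did not call the list (adjusted p = 0.548). Interferon response, immediate early, type 1 helper and cytokine genes were also called higher by camera, with adjusted p = 0.356, 0.101, 0.194 and 0.105 with an estimated correlation. Over the list alone the chemokine gene Cxcl10 (1.65, SE 0.43), the heat shock gene Hspa1b (1.28, SE 0.30) and Adm (1.54, SE 0.33) of the hypoxia list passed. The score of CD8 lineage markers lay at 3.68 ± 0.180 mean log2 CPM in these libraries against 3.33 ± 0.140 in wild type (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.760 over 19 measures).

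In CD8 heterozygotes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 8 of 12612 genes, 4 higher and 4 lower, and 218 had an unadjusted p under 0.05. Tmod3 fell from 221 ± 14.95 to 108 ± 5.26 CPM (SD, n = 4 each; log2 change -1.04, SE 0.07, edgeR quasi-likelihood adjusted p = 1.11e-05). Cd1d1 fell from 3.47 ± 0.405 to 1.56 ± 0.190 CPM (log2 change -1.15, edgeR quasi-likelihood adjusted p = 0.0289) and passed in 8 of 22 alternatives. Rps3a3 (6.41) and Tpm3-rs7 (3.59) rose and Rps3a1 (-0.98) and Tpm3 (-0.56) fell, on the log2 scale. Of the genes outside the naming rule, Gm8778 and 2010007H06Rik (4.08 ± 0.270 CPM) rose, and both were chosen after their values were seen. Replicates 1 and 2 alone, again females against males, gave 8 calls and replicates 3 and 4 alone gave 4. In neither did Cd1d1, Gm8778 or 2010007H06Rik pass, and Tpm3 did not pass in replicates 3 and 4. No member of the 27 lists was called by edgeR's test, over all genes or adjusted over the list alone. The 28 interferon response genes lay below wild type with a median of -0.46 (camera adjusted p = 8.43e-08, and adjusted p = 0.784 with an estimated correlation), and the unfolded protein response list had a median of -0.21 (camera adjusted p = 2.34e-06, and adjusted p = 0.410 with an estimated correlation). fry called 0 lists.

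**Figure D2:**
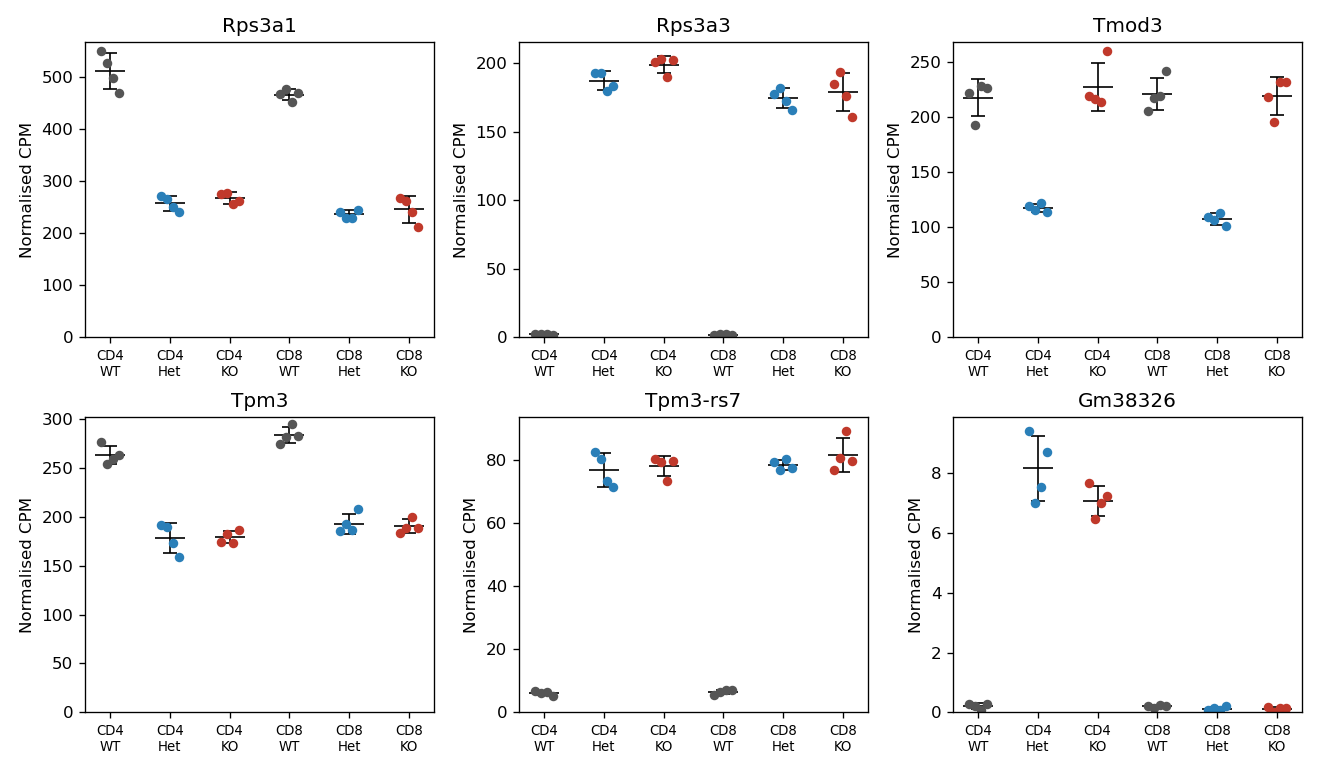
Normalised counts (CPM) per library of Rps3a1, Rps3a3, Tmod3, Tpm3, Tpm3-rs7 and Gm38326 by cell type and genotype, with bars for mean ± SD over 4 libraries. Rps3a3 and Tpm3-rs7 are high in heterozygotes and knockouts alike, Tmod3 is low in heterozygotes only (118 and 108 CPM in CD4 and CD8), and Gm38326 is high in the Cre carriers of CD4 only.

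Knockouts were also compared with heterozygotes, which asks about the second allele with Cre present on both sides. In CD4 cells edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2 of 12719 genes: Pou2af1, lower, and Tmod3, higher at 228 ± 21.8 against 118 ± 3.76 CPM (SD, n = 4 each; log2 change 0.95, SE 0.07, adjusted p = 0.000118). The genes of lowest p that did not pass were Spry1 (0.30), an inhibitor of growth factor signalling, Bckdk (0.48), a kinase of branched-chain amino acid breakdown, Utp4 (-0.20), of ribosome assembly, and Cdkn1a (-0.45), each with an edgeR quasi-likelihood adjusted p of 1.0. At an unadjusted p under 0.05 stood 461 genes. Replicates 1 and 2 alone gave 6 calls and replicates 3 and 4 alone gave 28. With sex and the difference between replicates 1 and 2 and replicates 3 and 4 as covariates 9 genes were called, and without a filter on low counts 1, which was Tmod3.

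In CD4 knockouts relative to heterozygotes camera called 6 lists lower, in a comparison that uses the same heterozygote libraries as the one above. Ifng had a log2 change of -0.97 (SE 0.41) and Prf1 -0.96 (SE 0.40). The cytotoxic and type 1 helper lists had camera adjusted p = 5.62e-05 each, and adjusted p = 0.175 and 0.195 with an estimated correlation. The p53, interferon, immediate early and cytokine lists had adjusted p = 0.340, 0.828, 0.175 and 0.297 with an estimated correlation. Of 15 p53 targets 0 passed over all genes, and Cdkn1a alone fell when adjusted over the list alone in edgeR's quasi-likelihood test. fry called 0 lists. The score of CD8 lineage markers lay at 3.43 ± 0.124 against 3.68 ± 0.180 mean log2 CPM (SD, n = 4 each; exact permutation p = 0.0857, adjusted p = 0.724 over 19 measures) and that of macrophage markers at 0.222 ± 0.00932 against 0.268 ± 0.0307 (exact permutation p = 0.0286, adjusted p = 0.543).

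In CD8 cells the same comparison gave 2 of 12612 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: Pou2af1, lower, and Tmod3, higher at 220 ± 17.3 against 108 ± 5.26 CPM (SD, n = 4 each; log2 change 1.03, SE 0.07, adjusted p = 3.74e-05). DESeq2 called 19, and 848 genes had an unadjusted p under 0.05 in edgeR. Genes of low p that did not pass were Lratd2 (0.48), Atf3 (1.06), Bag3 (-0.62), a cochaperone gene, and Slamf6 (-0.43), the edgeR quasi-likelihood adjusted p being 0.316 for Atf3 and 0.401 for Slamf6. All 4 passed with DESeq2 and in replicates 1 and 2 alone. Replicates 1 and 2 alone gave 246 calls and replicates 3 and 4 alone 2. Without a filter on low counts 5 genes were called, and without heterozygote replicate 3, 4 were called.

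Stress response genes were the list with the most members past its own adjustment in that comparison. Of 20 genes of the unfolded protein and integrated stress response 0 passed over all genes and 11 rose when adjusted over the list alone in edgeR's quasi-likelihood test, with 0 lower, including Atf3 (1.06, SE 0.19), Mthfd2 (0.51, SE 0.11), a mitochondrial folate enzyme gene, and Atf4 (0.49, SE 0.12), the central factor gene of that response. camera called the list higher (adjusted p = 9.59e-08, and adjusted p = 0.336 with an estimated correlation). The 28 interferon response genes had a median of 1.17 (camera adjusted p = 2.85e-21, and adjusted p = 0.454 with an estimated correlation), with 1 higher over the list alone, Rtp4 (1.59, SE 0.38). Over the list alone, Il12rb1 (0.51, SE 0.13) rose while Il18r1 (-0.69, SE 0.15) and Il18rap (-0.40, SE 0.09), the chains of the interleukin 18 receptor, fell among 12 type 1 helper genes. Cxcl10 (2.05, SE 0.50) rose and Ccl1 (-1.90, SE 0.53) fell among 23 cytokine genes, and Slamf6 and Cxcr5 (-0.55, SE 0.15) fell among 12 follicular helper genes. camera called cholesterol synthesis and oxidative phosphorylation lower and immediate early and activation genes higher, with adjusted p = 0.720, 0.879, 0.454 and 0.454 with an estimated correlation. fry called 0 lists.

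The knockout effect was compared between the cell types with a test of the difference itself. Gm38326 was the 1 call of 13288 genes, with 219 at an unadjusted p under 0.05 where chance gives 664. It stood at 0.115 ± 0.0792 CPM in CD8 knockouts and 0.212 ± 0.0407 CPM in CD8 wild type (SD, n = 4 each), near the floor, against 7.09 ± 0.503 CPM in CD4 knockouts. The difference was -5.82 on the log2 scale (SE 0.60, edgeR quasi-likelihood adjusted p = 2.09e-05), and the gene was chosen after its values were seen. Named genes that did not pass were Lins1 (0.46), Il18bp (0.59), Stambpl1 (0.25), Abcb1b (-0.32), Cacna2d1 (-2.02) and Marcksl1 (-0.41), each with an edgeR quasi-likelihood adjusted p of 1.0. Of the lists, camera called interferon response (median 0.26) and stress response (0.30) higher in CD8 and cholesterol synthesis (-0.26), p53 targets (-0.18) and cell cycle (-0.08) lower, each with adjusted p = 0.994 with an estimated correlation, and 0 members passed over all genes or over a list alone in edgeR's test. With the difference between replicates 1 and 2 and replicates 3 and 4 as a covariate 1 gene was called.

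The heterozygote effect was compared in the same way. Gm38326 was again the 1 call by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at 0.125 ± 0.0646 CPM in CD8 heterozygotes and 8.17 ± 1.09 CPM in CD4 heterozygotes (SD, n = 4 each; log2 difference -5.92, SE 0.60, adjusted p = 1.58e-05), and 527 genes had an unadjusted p under 0.05. With genotype and number together as a block 2 genes were called. Tmod3 did not pass. Named genes that did not pass were Egln2 (0.46), Zfp934 (0.58), Fam173a (0.48), Klrc2 (-3.30), Ehd4 (-0.39) and Cdkn1a (-0.57). Of 15 p53 targets 4 differed when adjusted over the list alone, lower in CD8, with Mdm2 at -0.30 (SE 0.09) and Pmaip1 at -0.75 (SE 0.22). Ifng (-1.41, SE 0.39) and Prf1 (-1.25, SE 0.36) differed likewise in the cytotoxic list. camera called 9 lists. The interferon (median -1.03), cytotoxic, immediate early, type 1 helper, p53, cytokine, CD8 lineage and stress response lists were called lower in CD8 and oxidative phosphorylation higher. The adjusted p with an estimated correlation was 0.242, 0.0631, 0.0631, 0.113, 0.242, 0.209, 0.297, 0.537 and 0.783 in that order. With that block as well, of genotype and number together, the cytotoxic list alone passed (adjusted p = 0.00767 with an estimated correlation, in a range of 0.00767 to 0.0645 over its alternatives). With the difference between replicates 1 and 2 and replicates 3 and 4 as a covariate 1 gene was called.

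Wild-type CD8 cells were compared with wild-type CD4 cells to describe the cell types as labelled. Of the CD8 lineage genes 7 of 7 were higher in CD8 cells, led by the coreceptor genes Cd8a at 675 ± 26.7 against 0.216 ± 0.175 CPM (log2 change 11.56, SE 0.23) and Cd8b1 (5.12, SE 0.15), in edgeR's quasi-likelihood test. Of 6 CD4 lineage genes 4 were lower, including the coreceptor gene Cd4 at 0.899 ± 0.643 against 477 ± 36.7 CPM (-9.10, SE 0.29), Cd40lg (-6.86, SE 0.23), the B cell helper ligand, and Zbtb7b (-4.40, SE 0.37), the CD4 lineage factor. Of 18 cytotoxic genes 11 were higher and 2 lower, with Prf1 (6.70, SE 0.27), Ifng at 263 ± 42.5 against 1.95 ± 1.10 CPM (7.08, SE 0.31) and Gzmb (5.89, SE 0.41), the granzyme B gene. Of 18 integrin and migration genes 12 were higher and 0 lower, with Cxcr6 (2.58, SE 0.25) and Ccr9, a gut homing receptor gene, at 3.84 ± 1.80 CPM where the CD4 libraries together held 1 count. Of 12 type 1 helper genes 7 were higher and 2 lower, with both interleukin 18 receptor genes, Il18rap (2.31, SE 0.11) and Il18r1 (2.46, SE 0.22), among the former.

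Genes higher in CD4 cells included those of help and costimulation. Of 20 activation genes 2 were higher and 9 lower in CD8 cells, with the OX40 receptor gene Tnfrsf4 at -1.56 (SE 0.13) and Nr4a1 at -1.02 (SE 0.15). Of 5 type 17 helper genes 0 were higher and 3 lower, with Rora at -1.95 (SE 0.38). Of 12 follicular helper genes 1 was higher, Cxcr5 (1.55, SE 0.27), and 5 lower, with Il6ra (-2.84, SE 0.14) and Btla (-2.0, SE 0.17). Further named genes were Xcl1 (7.75), Samd3 (7.06), St8sia6 (-6.94), Dnah7a (-6.51) and Adh1 (-5.43). Il2 lay at -4.53 (SE 0.46) and Pou2af1 at -0.47 (edgeR quasi-likelihood adjusted p = 0.146). Pou2af1 passed with the difference between replicates 1 and 2 and replicates 3 and 4 as a covariate (edgeR quasi-likelihood adjusted p = 0.0469) and with sex added (0.0391), in a range of 0.0391 to 0.364 over its alternatives. camera's adjusted p with an estimated correlation was 0.000839 for each lineage list, 0.00876 for cytotoxic genes, 0.00807 for migration, 0.0314 for type 1 helper, and 0.0338 each for activation, type 17 and follicular genes. With genotype and number together as a block as well, 4 of these 8 lists passed, both lineage lists, cytotoxic and activation genes. Migration, type 1 helper, type 17 and follicular genes did not (adjusted p of 0.0599 to 0.0808 with an estimated correlation).

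The camera calls that did not hold with an estimated correlation in that comparison were interferon response (0 higher and 18 lower of 28, as Isg20 at -2.34, SE 0.34), oxidative phosphorylation (14 and 0 of 27, as Sdhb at 0.47, SE 0.07), cell cycle (18 and 0 of 30, as Kif23 at 0.39, SE 0.06), hypoxia (0 and 4 of 17) and POU2AF1 partners and targets (1 and 5 of 9). Their adjusted p was 0.364, 0.307, 0.354, 0.742 and 0.0859 with an estimated correlation. Members higher and lower in the lists not called by camera were 1 and 6 of 15 for immediate early genes, 1 and 3 of 6 for type 2 helper, 3 and 10 of 20 for stress response, 2 and 5 of 13 for inhibitory receptors and 7 and 5 of 18 for naive and memory genes. They were 5 and 10 of 24 for cytokines, 3 and 4 of 12 for regulatory T cells, 4 and 3 of 12 for common T cell genes, 2 and 1 of 15 for p53 targets, 5 and 2 of 15 for B cell genes and 1 and 1 of 6 for dendritic cell genes. They were 0 and 0 of 20 for glycolysis, 0 and 0 of 20 for cholesterol synthesis and 0 and 0 of 5 for sex-linked genes. The B cell and regulatory lists had medians of -0.01 and -0.34 beside a camera direction of up. In all edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4143 of 13288 genes, 1946 higher and 2197 lower in CD8, and fry called 15 lists. With the difference between replicates 1 and 2 and replicates 3 and 4 as a covariate 5265 genes were called.

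The overlap of genotype effects was measured next. In CD4, 7 genes were called in both knockouts and heterozygotes against wild type, 5 higher and 2 lower, where independent lists would share 0.0033 and 0.000943. The log2 changes correlated across 12719 genes at r = 0.63 (rho = 0.54), genes not being independent replicates. Unchanged groups simulated against the same wild-type libraries gave r = 0.49, with at most 0 shared calls, and a covariance of 0.0315 against 0.0406 observed. The simulated libraries are independent, while CD4 libraries of 1 number deviate together, which the simulated values leave out. With the wild-type libraries split between the comparisons, r ran from -0.40 to 0.38 and 5 to 6 calls were shared. In CD8, 7 calls were shared, 4 higher and 3 lower, with r = 0.34 (rho = 0.147, simulated r 0.50), a covariance of 0.0173 (simulated 0.0287), and r from -0.17 to 0.17 with split controls. The knockout effects in CD4 and CD8, which share no libraries, had r = 0.34 over 12207 genes but rho = 0.0831, and shared 7 calls, 4 higher and 3 lower, where independent lists would share 0.00131 and 0.000983. CD4 and CD8 libraries of 1 number deviate together, which those values leave out, and no value for unchanged groups was computed for this pair. These were Pou2af1, Rps3a1, Tpm3, Rps3a3, Tpm3-rs7, Gm8778 and 2010007H06Rik.

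Flanking sequence can differ with genotype, since heterozygotes carry 1 unfloxed chromosome. By the genotype label knockouts and wild type both have both alleles floxed, so between them the test cannot bear on unfloxed sequence. Of the genes within 10 Mb of Pou2af1, 1 was called in CD4 knockouts, in CD8 knockouts and in CD8 heterozygotes against wild type, and it was 2010007H06Rik each time. By Fisher's exact test with Benjamini-Hochberg adjustment over comparisons the lowest adjusted p was 0.276. In CD8 the means of 2010007H06Rik were 0.581, 4.08 and 4.95 CPM in wild type, heterozygotes and knockouts. In CD4 they were 0.98, 4.42 and 9.37 CPM, the heterozygote change not being called. By the genotype label its level did not follow the number of unfloxed chromosomes, and its cause was not tested.

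Marker scores and library quality were set beside the genotypes. Mitochondrial genes took 2.75% to 4.14% of gene counts, ribosomal protein genes 2.19% to 2.82% and immunoglobulin genes 0.0161% to 0.0479%. With 4 against 4 libraries, 11 of the 19 measures would have to reach the smallest permutation p for any to pass after adjustment, so the adjusted threshold was nearly out of reach and no absence of a difference follows. The lowest adjusted p was 0.271 in CD4 knockouts against wild type, for total counts (13.2 ± 0.798 against 16.2 ± 3.74 M counts, exact permutation p = 0.0286) and for detected genes (19425 ± 212 against 20116 ± 696, exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The first principal component held 46.9% of the variance in CD4 and 34.8% in CD8 libraries. It parted replicates 1 and 2 from replicates 3 and 4 in every group, at -28.4 to -16.0 against 6.64 to 40.4 in CD4 and -40.7 to -6.21 against 7.96 to 27.8 in CD8.

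**Figure D3:**
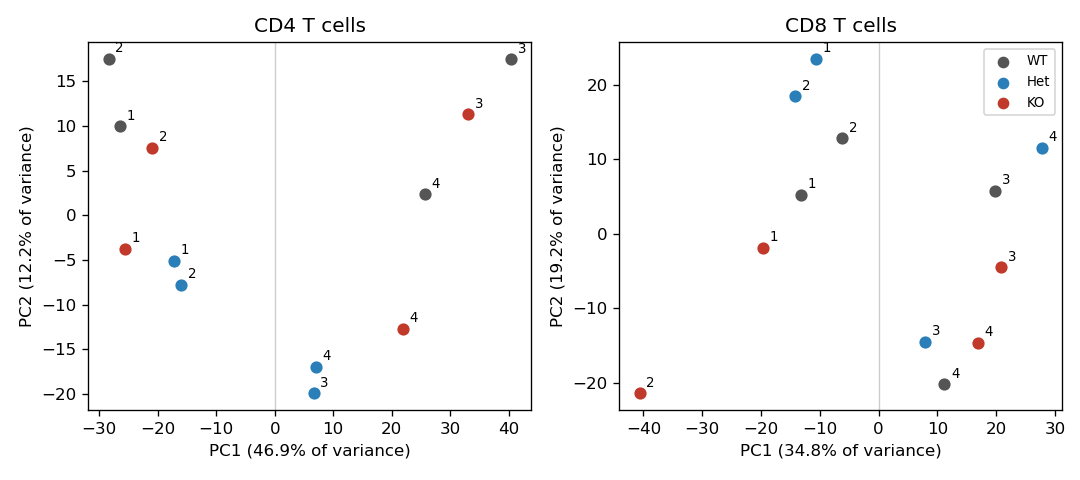
First and second principal components of log2 CPM within CD4 libraries and within CD8 libraries, with points coloured by genotype and numbered by replicate. The first component (46.9% and 34.8% of the variance) places replicates 1 and 2 on the negative side and replicates 3 and 4 on the positive side in both cell types.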

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

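The tests of reads that change place, of the dose of Pou2af1 and of Cre for Tmod3 were chosen after the results they measure had been seen. The tests of the intervals on chromosomes 3 and 9 and the counts of other splits were written down before their own results. Both intervals were set by genes already called in these data: the called genes of chromosome 3, and Pou2af1 to Tmod3.

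Rps3a1 and Tpm3 were lower and their copies Rps3a3 and Tpm3-rs7 higher in every Cre carrier group. A graded dose effect of Pou2af1 is argued against. Over the 4 genes and both cell types, knockouts and heterozygotes differed by a median of 0.0501 and at most 0.0869 on the log2 scale. Knockouts and wild type differed by a median of 2.29 and at least 0.562. An effect complete on loss of 1 allele would give the same levels in both Cre carrier groups. This comparison cannot tell such an effect apart from Cre. Reads that change place between a gene and its copies may account for the pattern. The summed counts of each family kept at most a share of 0.192 of the change of the gene alone (Rps3a family in CD4, 518 ± 34.9 CPM in wild type and 458 ± 20.7 CPM in Cre carriers). Sequence of chromosome 3 carried with the Cre transgene is a candidate source of such a shift, since between 60769887 and 90100902 (GRCm38) 3 of 139 other genes, against 13 of 12056 elsewhere, were at an unadjusted p under 0.05 the same way in both cell types (Fisher's exact p = 0.000728). That rests on Rnu73b (which lies inside Rps3a1), Gm37116 and Ube2q1, and without overlapping genes it is 2 of 137 (Fisher's exact p = 0.012). The interval spans the called genes of chromosome 3, which the count leaves out. Cd1d1, Gm33707 and Gm38326 are among them, and Gm38326 was high in the Cre carriers of CD4 only. Regulatory sequence of the transgene itself was not tested.

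Tmod3 was lower in heterozygotes than in both other genotypes. The Cre transgene and the dose of Pou2af1 are both argued against, since the change in knockouts was 0.0565 in CD4 (95% interval -0.0973 to 0.210) and -0.01 in CD8 (-0.165 to 0.145), against -0.90 and -1.04 in heterozygotes. By the genotype label heterozygotes alone carry an unfloxed chromosome 9 (by the titles wild type would carry 2), and sequence there that differs from the floxed one may lower Tmod3, which lies on that chromosome with Pou2af1. Of 160 genes between them 0 were at an unadjusted p under 0.05 the same way in both cell types (Fisher's exact p = 1), and 0.213 would be expected, too few for this count to decide. So such a sequence effect cannot be told apart from other causes limited to heterozygotes, and no biological cause but the dose of Pou2af1 was tested.

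Gm38326 differed between cell types in its response, by -5.82 for the knockout and by -5.92 for the heterozygote on the log2 scale, in edgeR's quasi-likelihood test of the difference, and no cause was tested for it. Lists whose knockout effect differed between cell types by camera with the preset correlation were cell cycle (adjusted p = 0.0171), cholesterol synthesis (0.000376), type I interferon response (0.00319), unfolded protein and integrated stress response (0.0401) and p53 targets (0.00319). For the heterozygote effect they were type 1 helper (adjusted p = 0.000580), cytotoxic effector (6.87e-06), cytokines and chemokines (0.0455), oxidative phosphorylation (0.0293), type I interferon response (2.38e-16), unfolded protein and integrated stress response (0.0190), p53 targets (0.000340), immediate early genes (0.000569) and CD8 lineage markers (0.0341). With camera's estimated correlation the adjusted p was 0.994 for each of the 5 knockout lists and 0.0631 to 0.783 for the 9 heterozygote lists.

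About 1 in 20 groups of independent, normally distributed values would hold a single library far from the other 3, or 9.9 of 198. The values here are related between measures and some rest on few counts, so 9.9 is a rough guide only. Single libraries stood far from the other 3 of their group in 19 of the 198 groups of values. In marker scores (mean log2 CPM) these were common T cell genes in CD4_WT replicate 3 (highest, 7.93), dendritic cell genes in CD4_KO replicate 3 (highest, 1.70), erythroid genes in CD4_KO replicate 3 (highest, 0.0290), neutrophil genes in CD8_WT replicate 1 (highest, 0.0308) and CD8_KO replicate 1 (highest, 0.00845), and NK cell genes in CD8_WT replicate 4 (lowest, 0.745). In library measures they were the mitochondrial share of CD8_KO replicate 4 (lowest, 3.55%), the total of CD4_WT replicate 4 (highest, 21.8 megacounts) with its 21157 detected genes (highest), and the total of CD8_KO replicate 1 (highest, 16.6 megacounts). Among genes they were Pou2af1 in CD8_Het replicate 2 (lowest, 13.4 CPM), Rps3a3 (lowest, 189.9 CPM) and Tpm3-rs7 (lowest, 73.4 CPM) in CD4_KO replicate 3, and Tmod3 in CD4_KO replicate 4 (highest, 260.3 CPM). Among genes of low count they were Gm33707 in CD4_Het replicate 2 (lowest, 1.40 CPM), CD8_WT replicate 4 (highest, 0.0689 CPM) and CD8_Het replicate 4 (highest, 0.140 CPM), Gm8778 in CD8_WT replicate 3 (highest, 0.0638 CPM) and 2010007H06Rik in CD8_WT replicate 1 (lowest, 0.0756 CPM). Of these low-count values, all but that of CD4_Het replicate 2 lay under the floor of 3 counts.

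Each comparison was repeated over the 35 splits of its 8 libraries (for differences between cell types, the same split in the 8 libraries of each cell type). As many genes were called in 1 of the 35 splits, the real one, for CD4 heterozygote against wild type (11, highest other 1), CD4 knockout against heterozygote (2, highest other 0), the heterozygote effect between cell types (1, highest other 0) and CD8 against CD4 wild type (4143, highest other 1). As many were called in 2 for CD4 knockout against wild type (9, highest other 4551) and the knockout effect between cell types (1, highest other 345). In these 6 comparisons same-numbered libraries deviate together, which in CD4 does not by itself show pairs. The 8 splits that part every same-numbered pair are too few for a share under 0.05. For both effects between cell types these splits part numbers within a cell type, not the CD4 library from the CD8 library of 1 number. The highest other of those 8 was 0 genes, or 1 gene for CD8 against CD4 wild type. For the CD8 comparisons chance cannot be excluded by the count of splits: knockout against wild type (8, in 2 splits, highest other 499), heterozygote against wild type (8, in 2 splits, highest other 66) and knockout against heterozygote (2, in 2 splits, highest other 1103). In the 5 comparisons with 2 splits the other is replicates 1 and 2 against replicates 3 and 4, which points to a structure of the samples. The remaining 33 splits of each called 0 genes, so a share over 0.05 rests there on that 1 split. The replicate block called 9 genes in CD4 knockout against wild type, 1 in the knockout effect between cell types, and 7, 7 and 2 in the CD8 comparisons.

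Lists called by camera with the preset correlation were counted in the same way, and by this count chance is not excluded in the genotype comparisons. As many lists were called in 29 of 35 splits for CD4 knockout against wild type (2 lists, highest other 10), 19 for CD8 knockout against wild type (5, highest other 10), 16 for CD4 heterozygote against wild type (6, highest other 11), 30 for CD8 heterozygote against wild type (2, highest other 10), 16 for CD4 knockout against heterozygote (6, highest other 10) and 20 for CD8 knockout against heterozygote (6, highest other 12). They were called in 10 splits for the knockout effect between cell types (5, highest other 8), 7 for the heterozygote effect (9, highest other 11) and 7 for CD8 against CD4 wild type (13, highest other 16). The 6 other splits of that last count each keep 3 of 4 libraries of a cell type together, and so part of the difference between cell types, while the splits of 2 and 2 called at most 6 lists and 8 lists passed with an estimated correlation, or 4 with the replicate block as well. The count of splits therefore decides nothing for that comparison. Among the 8 splits that part every pair, the highest other was 4, 8 and 10 lists in CD4 (knockout and heterozygote against wild type, then knockout against heterozygote), and 4, 7 and 16 between cell types (knockout effect, heterozygote effect, wild type).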

How the results depend on the processing

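The fits that use replicates 1 and 2 against replicates 3 and 4 (as a covariate, with sex, or each set alone) and the replicate block with an estimated correlation were chosen after the data had been seen, and the others were planned. Of 1740 values of named genes under alternatives, 1640 kept direction and side of the threshold, 74 kept direction and lost the threshold, 17 gained it and 9 reversed. The cause was not tested for the changes below, except that fewer libraries leave fewer degrees of freedom. With about 14.0 megacounts per library, genes under the floor of 0.138 to 0.251 CPM are beyond reach. Genes above that floor that filterByExpr left out (its default count of 10) were not tested in the main fits either. In simulated CD4 knockouts, drawn as independent libraries, edgeR recovered 46.3% of 1.5-fold changes.

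For gene counts, DESeq2 gave 80 in CD4 heterozygote against wild type and 19 in CD8 knockout against heterozygote. All 24 libraries in one fit gave 18 in CD4 heterozygote against wild type, the covariate for replicates 1 and 2 against 3 and 4 gave 82 there, and with sex added 507, with 15 in CD4 knockout against wild type and 9 in CD4 knockout against heterozygote. Without a filter on low counts CD4 knockout against heterozygote gave 1 and CD8 knockout against heterozygote 5. Replicates 1 and 2 alone gave 365 in CD4 heterozygote against wild type (females against males), 6 in CD4 and 246 in CD8 knockout against heterozygote, and 5 in CD8 knockout against wild type. Replicates 3 and 4 alone gave 103 in CD4 and 4 in CD8 heterozygote against wild type, 28 in CD4 knockout against heterozygote and 5 in CD8 knockout against wild type.

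The replicate block gave 58 genes in CD4 heterozygote against wild type, in place of 11, and 2 in the heterozygote effect between cell types, in place of 1. It brought Pou2af1 in CD4 heterozygotes past the threshold (adjusted p = 0.00162, range 7.39e-05 to 0.754) and gave 4 lists by camera in CD4 knockout against wild type. It changed the call of no other named gene of the CD4 comparisons or of those between cell types, and moved no other count of theirs by over 1.5 times, apart from the lists with an estimated correlation. In CD8 genotype comparisons, where the libraries share only a number, the block gave 7, 7 and 2 genes, without Cd1d1, and a library was closest to its own number in 3, 0 and 3 of 4 pairs (knockout with wild type, heterozygote with wild type, knockout with heterozygote), as in 2, 3 and 1 of 4 in CD4, so that hint does not set CD4 apart.

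Leaving out 1 library at a time gave 8 to 9 genes in CD4 and 7 to 8 in CD8 knockout against wild type, 7 to 9 in CD4 and 7 to 8 in CD8 heterozygote against wild type, 2 to 2 in CD4 and 2 to 4 in CD8 knockout against heterozygote, 1 to 1 in each effect between cell types and 3150 to 3993 in CD8 against CD4 wild type. CD4 heterozygote against wild type fell to 7 without CD4_WT replicate 3 or CD4_Het replicate 1, and CD8 knockout against heterozygote rose to 4 without CD8_Het replicate 3, with Lratd2 past the threshold (adjusted p = 0.00547, range over alternatives 0.00308 to 0.998). In CD4 heterozygotes Cdkn1a was lost without any 1 library but CD4_WT replicate 4 (edgeR's adjusted p 0.0699 to 0.130), Ehd4 without any 1 (0.0667 to 0.200), Neat1 without any 1 but CD4_WT replicate 2 (0.0625 to 0.200), and Gm8778 without CD4_WT replicates 3 or 4 or CD4_Het replicate 1 (0.0544 to 0.0595). Cd1d1 was lost in CD8 heterozygotes without any 1 library but CD8_WT replicate 1 (adjusted p 0.0531 to 0.174), and in CD8 knockouts without any 1 but CD8_WT replicate 1 or CD8_KO replicate 4 (0.0626 to 0.104). 2010007H06Rik was lost in CD4 knockouts without CD4_WT replicate 4 (adjusted p = 0.0510, range over alternatives 3.06e-12 to 0.0757). The difference of Pou2af1 between cell types, not called, ran up to 0.53 for the knockout (without CD4_KO replicate 3) and 0.23 for the heterozygote (without CD8_WT replicate 3). It reversed for the knockout to -0.0219 without CD4_WT replicate 4, -0.0657 and -0.00441 without CD4_KO replicates 1 and 2, and -0.0151 and -0.0777 without CD8_KO replicates 1 and 2. For the heterozygote it reversed to -0.0062 and -0.0499 without CD4_WT replicates 3 and 4, -0.0109 without CD4_Het replicate 1 and -0.00101 without CD8_WT replicate 1.

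For lists called, an estimated correlation and fry each gave 0 in all 8 comparisons that involve genotype, and an estimated correlation gave 8 in CD8 against CD4 wild type. An estimated correlation with the covariates for replicates 1 and 2 against 3 and 4 and for sex gave 1 in CD4 heterozygote against wild type, 1 in CD4 knockout against heterozygote, 8 in CD8 against CD4 wild type and 0 in the others. With the replicate block it gave 1 in the heterozygote effect between cell types, 4 in CD8 against CD4 wild type and 0 in the others. camera with the covariate for replicates 1 and 2 against 3 and 4 gave 4 in CD4 knockout against wild type. With sex added it gave 4 there, 12 in CD4 heterozygote against wild type and 11 in CD4 knockout against heterozygote.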

Other observations

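The comparison of replicates 1 and 2 with replicates 3 and 4 and the test of sex were chosen after the first principal component had been seen, while the test of a shared day was written down before its result. In replicates 3 and 4, genes of the low-oxygen response and of glycolysis were higher in both cell types. Of 20 glycolysis genes 20 were higher in CD4 and 19 in CD8, with Slc2a1, the glucose transporter gene, at 1.01 (SE 0.15) and 1.11 (SE 0.17) on the log2 scale. Of the hypoxia genes 15 of 17 were higher in CD4 and 12 of 16 in CD8, with Egln3 at 2.64 (SE 0.54) and 3.62 (SE 0.33) and Bnip3, of mitochondrial autophagy, at 2.75 (SE 0.30) and 3.06 (SE 0.49), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 20 cholesterol synthesis genes 18 were higher in CD4 and 0 in CD8. Markers of other cell types moved along the same split: in CD8, B cell markers were 0 higher and 7 lower of 13 (median -0.69) and dendritic cell markers 0 higher and 5 lower of 6 (median -0.99), while in CD4 B cell markers were 3 higher and 0 lower of 13 (median 0.45) and dendritic cell markers 1 higher and 0 lower of 5 (median -0.20). In all 4411 genes differed in CD4 (2280 higher and 2131 lower in replicates 3 and 4) and 2228 in CD8 (1130 and 1098), more than in any genotype comparison of edgeR, and these sets of samples were read from the data and are not groups of the study.

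Sex is argued against as the cause of that difference: 8 of 16 pairs of libraries of 1 genotype, cell type and sex lay on opposite sides of the first component. A day of culture or preparation shared by the numbers may be the cause. The changes correlated across 11799 genes between CD4 and CD8 libraries at r = 0.597 (rho = 0.486), genes not being independent replicates. A shared day cannot be told apart from a difference between the mice, since the labels do not say whether a number marks a day, a mouse or both.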
